A study of Faecalicatena contorta and Faecalicatena fissicatena and Bacteroides thetaiotaomicron with 24 samples.

How the data were processed

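The data were RNA-seq profiles of 5 human gut bacterial strains from 4 species, each grown to mid-log phase on a seaweed polysaccharide at 5 mg per ml or on galactose as the only carbon source. Cells were pelleted, RNA was stabilised and extracted with a column kit, ribosomal RNA was depleted, and libraries were read on an Illumina HiSeq instrument, per the labels' protocols. There were 24 libraries in 12 groups of 2, and every group was taken from the carbon source in the labels. No label says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

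The deposited values were RPKM (read counts divided by gene length and library total) per library, in 1 table per strain, per the file headers. A locus without reads was listed at a constant floor of its table, between 0.009 and 0.023 RPKM. The authors' tables also held a fold column, which was the ratio of the geometric mean RPKM on a polysaccharide to that on galactose. For strains 3731 and 18002P the deposited tables held a p-value column, whose values differed by a median of 0.00174 and 0.00176 from a Benjamini-Hochberg adjusted p of an equal-variance test on log2 RPKM recomputed from the same columns. The last deposited column of those tables was a score headed T value, with galactose minus polysaccharide as its direction. DESeq2 was named as a tool, per the submitters' processing notes, but no column held its output or read counts. The aligner, the counting tool, the genome builds and the annotations are not given in the sources used here. RPKM depends on the library total, so a few very abundant loci lower the values of all others in that library.

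The design written before the data were examined foresaw a count model. Since the unit was RPKM, a linear model on log2 values took its place: limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on mean), 1 fit per strain over all of its groups, on log2(scaled RPKM + 1), with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. Loci with at least 1 RPKM in at least 2 libraries were tested. Libraries were scaled within a strain by the median ratio to the geometric mean over loci of at least 10 RPKM in every library, which used between 2340 and 3378 loci and gave factors from 0.6962 to 1.59. Fold changes are on the scale of log2(RPKM + 1), which understates changes of low loci. The pseudocount, the level of the filter, the trend and the scaling were chosen after the values had been seen and after trial fits without scaling at pseudocounts of 0.1, 1 and 5, with and without the trend; the calls under the scaling had not been seen when it was chosen, and the unscaled calls are given as an alternative. The scaling moved the median log2 fold change of all tested loci, from the deposited RPKM to the scaled values, from -0.20 to -0.02 in 18002P, from -0.21 to 0.05 and from -0.25 to -0.04 in 548 on agarose and porphyran, from -0.05 to 0.12 and from 0.22 to 0.03 in D5 on agarose and porphyran, and from -0.25 to 0.11 between them. Quantile normalization moved it from 0.47 to -0.07 in 3731, from -0.02 to -0.19 in 18002P, from 0.05 to -0.14 in 548 on agarose and from 0.09 to -0.07 between its polysaccharides, from 0.13 to -0.07 in 588, and from 0.12 to -0.11 in D5 on agarose and from 0.11 to -0.04 between its polysaccharides.

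Each table had its own loci and was tested only within itself. The tables give locus tags without product names, except 17 rows of strain 3731 that carry gene symbols instead, and the files do not pair the tags with gene names. The lists of gene functions fixed beforehand could therefore not be applied to any comparison. Loci were ordered by the number in their tag. A run was defined beforehand as at least 4 called loci changed at least 5-fold in the same direction with at most 2 other loci between neighbours, and the number of runs was set beside 1000 random shuffles of the locus order. The shuffles move loci singly, so they break up neighbours that vary together for any reason. More runs than in shuffled orders therefore show only that called loci cluster in tag order, not why. Breaks between contigs are not marked, so a run is a neighbourhood in tag order. The rule for named loci fixed beforehand allowed, for IDs without product text, at most 2 that rose and 2 that fell per comparison: those with the largest called changes and a mean of at least 10 RPKM. The rows with symbols are given because they are the only ones with names, a choice made after their values were seen.

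Overlaps of the agarose and porphyran responses share their galactose libraries. Each was therefore set beside 100 simulated sets of unchanged groups and beside the overlap of independent lists. In a fit added after the results were seen, each polysaccharide was also set against 1 of the 2 galactose libraries, in both ways.

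Absolute depth is unknown, because no totals of reads were given. Low values of a locus stood in near whole-number ratios between libraries, which gave the relative depth within a strain; between 30.9% and 70.6% of low loci came out whole within 0.12 reads, against 1.2% to 9.5% when the steps were broken on purpose. Relative to galactose replicate 1 of the same strain, the other libraries stood between 0.813 and 1.712. The check of whole numbers rested on 17 low loci in 3731, 307 in 18002P, 292 in 548, 166 in 588 and 356 in D5. The relative depth itself used, for each pair of libraries, the loci above the floor and under 2 RPKM in both. In low loci 1 read was worth about 0.092 to 0.509 RPKM. Since the whole share was well under all loci, read counts were not rebuilt and no count model was run.

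Calls in 5 of the comparisons, the relative depth and the runs were tested on simulated data; calls in 548 and D5 on porphyran and between agarose and porphyran were not, and the simulated overlaps held only unchanged groups. With 200 changed loci, 66 or 67 per fold size, the share called at 5-fold was 70.1% for strain 3731, 100% for 18002P, 56.7% for 548 on agarose, 13.4% for 588 and 71.6% for D5 on agarose; at 2-fold it was 10.4%, 91%, 2.99%, 0% and 1.49%. The numbers of unchanged loci called were 7, 16, 4, 2 and 4. The simulated values were independent and normal, with the same spread in every group. In the data the groups differed in spread. After centring, the median absolute log2 difference between libraries was 0.165 on galactose and 0.48 on carrageenan in 3731. In 588 it was 0.355 on galactose and 0.938 on porphyran. The simulation therefore does not show how calls behave where the spread is unequal. The step for relative depth recovered 19 of 19 simulated depths within 2%, and the step for runs recovered 20 of 20 planted sets. Alternatives were other pseudocounts, filters, scalings and thresholds, fits on the compared groups only, the replicate number as a block, and leaving out each library. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.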

Results

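Transcript levels were measured by RNA-seq in 5 strains of human gut bacteria. Bacteroides thetaiotaomicron 3731 was grown on lambda-carrageenan, Bacteroides xylanisolvens 18002P on porphyran, Faecalicatena contorta 548 and Faecalicatena fissicatena D5 on low-melt agarose and on porphyran, and Faecalicatena contorta 588 on porphyran. Every strain was also grown on galactose. Carrageenan, agarose and porphyran are galactose-based polysaccharides of red algal cell walls. The comparisons ask which loci differ between growth on a polysaccharide and on free galactose. They cannot tell the polymer form from other differences between these carbon sources. Each of the 12 groups had 2 libraries. The tables listed 5523 loci for strain 3731, 5091 for 18002P, 5047 for 548, 4941 for 588 and 4621 for D5. Library totals of reads are not known, and the relative depth within a strain spanned 0.878 to 1.625 in 3731, 1 to 1.357 in 18002P, 0.813 to 1.199 in 548, 1 to 1.712 in 588 and 0.826 to 1 in D5. In the Bacteroides tables and in the Faecalicatena tables the libraries carry different series of codes, which follow the genus and not the carbon source within a strain.

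On carrageenan, a block of neighbouring loci in B. thetaiotaomicron 3731 from tag number 14765 to 15040 rose, with 50 of its 54 loci called at 5-fold or more and a median log2 fold change of 4.16. The median RPKM of these 50 loci was 6.1 and 6.2 on galactose and 322.5 and 261.1 on carrageenan (n = 2 each). A second block, from 26280 to 26375, rose more steeply, with 18 of 20 loci called and a median log2 fold change of 7.13. Its median RPKM went from 5.3 and 4.1 to 576.2 and 633.9. Among shorter runs, the 8 called loci of 28720 to 28790 rose with a median of 5.20, from 2.5 and 0.5 RPKM to 93.3 and 149.8. The 8 loci of 7850 to 7885 rose with a median of 4.42, and the 9 called loci of 20865 to 20915 with a median of 3.40.

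The most strongly raised locus of strain 3731, AMN69_RS15040, was at 1.69 and 1.62 RPKM on galactose and 973 and 1050 on carrageenan, a log2 fold change of 8.57 ± 0.26 (SE, limma adjusted p = 0.00011). AMN69_RS26340 rose by 8.24 ± 0.26, with the same adjusted p. Falling runs numbered 2. The 10 called loci between 11900 and 11965 had a median log2 fold change of -3.24, and 4 of the 10 were called without galactose replicate 1 and 4 without replicate 2. The 5 between 9470 and 9490 had a median of -2.82. AMN69_RS11965, in the first of these runs, fell from 94.7 and 108 RPKM to 2.44 and to the table's floor of 0.023 (log2 fold change -5.81 ± 0.64, adjusted p = 0.00375), and AMN69_RS18145 from 1200 and 226 RPKM to 10.5 and 7.66 (-5.71 ± 0.77, adjusted p = 0.00612).

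Only strain 3731 had rows with gene symbols, 12 symbols over 17 rows, chosen here after their values were seen. Among the rows that rose were asnB, an asparagine synthetase, with a log2 fold change of 3.0 ± 0.59 (limma adjusted p = 0.0175), and aspA, an aspartate ammonia-lyase, with 1.79 ± 0.34 (adjusted p = 0.0167). For gpmA, a phosphoglycerate mutase of glycolysis, the 2 rows moved apart: one rose by 2.33 ± 0.22 and the other fell by 2.08 on the log2 scale, and the files do not say how the rows differ. The row for sdhA, the flavoprotein subunit of succinate dehydrogenase, fell from 1620 and 1680 RPKM to 424 and 539 (log2 fold change -1.79 ± 0.24, adjusted p = 0.00577). Smaller decreases were called for aroE, a shikimate dehydrogenase (-1.27), glyA, a serine hydroxymethyltransferase (-0.91), and fkp, which makes GDP-fucose (-0.97). All 5 rows of rrf, the 5S ribosomal RNA, were lower, with a log2 fold change of -1.95 for 1 row and of -2.31 for 4 rows with identical values; after ribosomal depletion their RPKM describes the RNA left over. The RNA component of RNase P, rnpB, stood at 22300 and 22800 RPKM on galactose and 25400 and 31100 on carrageenan (log2 fold change 0.31 ± 0.37, adjusted p = 0.53). The transfer-messenger RNA ssrA (0.03 ± 0.39), the translocase secA (-0.53 ± 0.17) and the epimerase araD (-0.21 ± 0.59) did not pass the test.

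Several of the calls on rows with symbols in strain 3731 were lost in other fits. Without galactose replicates 1 and 2, fkp (limma adjusted p = 0.223 and 0.232), glyA (0.12 and 0.131) and the rrf rows with identical values (0.325 and 0.083) missed the threshold, and the other rrf row missed it without replicate 1 (0.199). In these fits the log2 fold changes were -0.95 and -1.01 for fkp, -0.90 and -0.94 for glyA, -1.85 and -2.80 for the identical rrf rows and -1.42 for the other. Fits without a carrageenan library took their spread from galactose alone, so only the log2 fold changes are given for them. For secA these were -0.57 without carrageenan replicate 1 and -0.48 without replicate 2. For araD the log2 fold change was -1.04 without carrageenan replicate 1 and 0.62 without replicate 2. With a background subtracted, asnB (adjusted p = 0.0715), aspA (0.0569), aroE (0.0896), fkp (0.0944) and the rrf row with the smaller change (0.061) missed the threshold. With quantile normalization asnB had 1.87 (adjusted p = 0.14), with RPKM as deposited fkp had an adjusted p of 0.0626, and without the variance trend aroE (0.0915), aspA (0.0619), fkp (0.0984), glyA (0.0741) and the rrf rows (0.0674 and 0.0748) were not called. Without the low filter, aroE (0.058), fkp (0.063) and the identical rrf rows (0.0684) missed the threshold too.

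Over the genome of strain 3731, 819 loci were higher and 603 lower on carrageenan of 5388 tested, and 337 and 67 of these changed at least 5-fold. Of the 337, the 335 with a tag formed 15 runs with 151 loci, where shuffled orders gave at most 8 runs. Here and in the other strains, the shuffles moved single loci, so the excess shows clustering in tag order and not its source. Quantile normalization gave 530 higher and 714 lower, with a median log2 fold change over all loci of -0.07 in place of 0.47. The loci in rising runs made up 0.27% and 0.20% of summed RPKM on galactose and 4.01% and 4.51% on carrageenan. The carrageenan libraries differed most at the low end, with a 10th percentile of 9.24 RPKM in replicate 1 and 3.30 in replicate 2, against 1.76 and 0.638 on galactose. In strain 3731, 876 and 705 loci were called without galactose replicates 1 and 2, and 2464 and 3325 without carrageenan replicates 1 and 2. Rising runs held 440 loci without carrageenan replicate 2. With 1 carrageenan library left, the spread came from the galactose libraries alone. These differed less, with a median absolute log2 difference of 0.165 after centring against 0.48 on carrageenan. With a background subtracted, 549 loci were higher and 469 lower. All 50 loci of the longest run, all 18 of the second and all 8 of 7850 to 7885 stayed called. Weaker were 3805 to 3855 (1 of 8 called), 4330 to 4355 (2 of 4) and 13865 to 13920 (3 of 8). So were 22415 to 22445 (2 of 6), 23460 to 23495 (2 of 4) and 25645 to 25675 (3 of 6). Among the other rising runs, 8270 to 8285 kept 3 of 4, 12575 to 12595 4 of 5 and 13790 to 13845 6 of 8. The run 16080 to 16105 kept 4 of 5, 20865 to 20915 6 of 9 and 28720 to 28790 6 of 8.

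**Figure D1:**
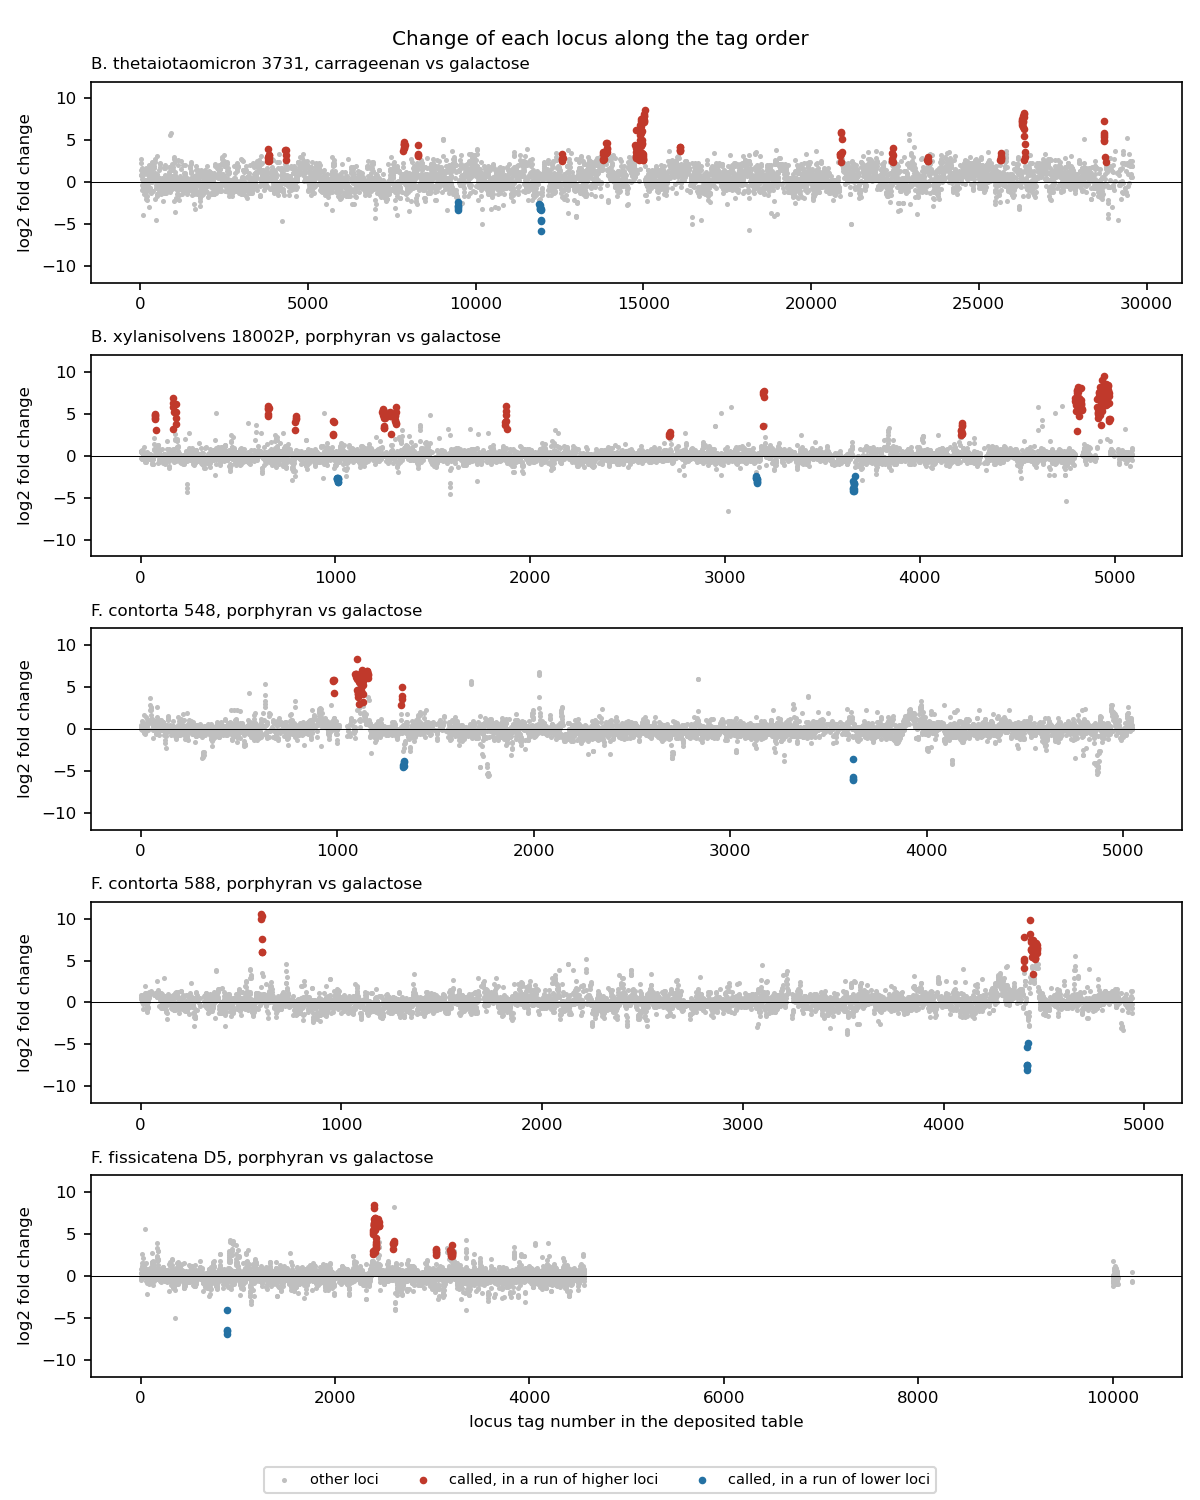
Log2 fold change of each tested locus (vertical axis) against its tag number in the deposited table (horizontal axis), for 1 polysaccharide per strain against galactose, with 2 libraries per group. Red points are called loci in runs that rose and blue points those in runs that fell; in strain 18002P the red points gather from 4797 to 4831 and from 4910 to 4974.

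In B. xylanisolvens 18002P on porphyran, 2 long blocks of neighbouring loci rose. From tag number 4910 to 4974, 63 of 65 loci were called with a median log2 fold change of 6.78, and from 4797 to 4831 all 35 loci were called with a median of 6.22. The median RPKM of the first block was 3.5 and 4.0 on galactose and 553.3 and 506.9 on porphyran, and that of the second 5.0 and 5.8 against 470.7 and 399.2. The 5 loci of 3195 to 3199 rose more steeply, with a median of 7.34, from 6.4 and 4.2 RPKM to 1172.7 and 1047.3. Another 15 called loci between 1241 and 1257 rose with a median of 4.86.

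The locus 017303E_unicycler_bold_04945, inside the longest run, rose from 1.60 and 1.85 RPKM to 1910 and 1540, a log2 fold change of 9.47 ± 0.14 (SE, limma adjusted p = 5.21e-07), and 017303E_unicycler_bold_04934 by 8.96 ± 0.14. Falling runs covered 3656 to 3665 with 10 loci (median log2 fold change -3.65), 1007 to 1016 with 9 (-2.80) and 3159 to 3166 with 8 (-2.78). Outside these runs, 017303E_unicycler_bold_03014 fell from 13000 and 18400 RPKM to 146 and 124 (log2 fold change -6.63 ± 0.20, adjusted p = 2.76e-06), while 017303E_unicycler_bold_04751 fell by 5.36 on the log2 scale (adjusted p = 0.000947).

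Of 4775 loci tested in strain 18002P, 1042 were higher and 1056 lower on porphyran. At 5-fold or more, 224 were higher and 43 lower, and 80.4% of the 224 lay in 15 runs, where shuffled orders gave at most 3. Rising runs took 0.19% and 0.18% of summed RPKM on galactose and 8.08% and 6.88% on porphyran. The split of all calls moved with the scaling: 49.7% of calls were higher with the scaled values, 31.5% (743 higher, 1618 lower) with RPKM as deposited and 29.4% (682 higher, 1636 lower) with quantile normalization. Without galactose replicate 1 there were 1393 calls. Every called locus of the 18 runs was called whichever library was left out.

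On agarose, 4 blocks of neighbouring loci between tag numbers 1093 and 1157 rose in F. contorta 548. The 17 called loci of 1093 to 1112 had a median log2 fold change of 6.07, the 16 of 1118 to 1135 one of 5.28, the 4 of 1140 to 1145 one of 2.74 and the 7 of 1151 to 1157 one of 6.96. In the last of these blocks the median RPKM was 19.2 and 24.9 on galactose and 2248.9 and 3296.9 on agarose. The 4 loci of 980 to 983 rose with a median of 6.10, and the 6 called loci of 48 to 54 with a median of 5.74. Of the 4 loci of 1140 to 1145, 1 was called with RPKM as deposited.

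The largest increases in strain 548 on agarose were those of 017301E_01127, from 13.2 and 15.2 RPKM to 17400 and 8120 (log2 fold change 9.89 ± 0.66, limma adjusted p = 0.00142), and 017301E_01126, by 9.17 ± 0.39 (adjusted p = 0.000373). A run of 5 loci at 1336 to 1340 fell with a median of -4.60, from 1297.5 and 1248.0 RPKM to 41.3 and 52.6. The 4 loci of 3624 to 3627 fell with a median of -5.88; the largest decreases among named loci were those of 017301E_03626 (-6.0 ± 0.59, adjusted p = 0.00527) and 017301E_03625 (-6.0 ± 0.67, adjusted p = 0.00945). Without galactose replicate 2, agarose replicate 1 or agarose replicate 2, 017301E_03626 missed the threshold (adjusted p = 0.0548, 0.0796 and 0.0545). For 017301E_03625 the adjusted p was 0.0609 and 0.0771 without galactose replicates 1 and 2 and 0.0977 and 0.0701 without agarose replicates 1 and 2. In these fits the log2 fold changes were -5.54, -5.60 and -6.39 for the former and -6.43, -5.57, -5.56 and -6.43 for the latter.

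In total 105 loci of strain 548 were higher and 18 lower on agarose of 4718 tested, and 68 of the 99 higher at 5-fold or more lay in 9 runs, where shuffled orders gave at most 1. In place of these 123 calls there were 28 and 33 without galactose replicates 1 and 2 and 28 and 25 without agarose replicates 1 and 2, while a fit on these groups alone gave 333. Rising runs held 18 and 24 loci without galactose replicates 1 and 2 and 17 without either agarose library. Of the 17 called loci of 1093 to 1112, 8, 8, 8 and 7 passed the test in these fits, in the same order, of the 16 of 1118 to 1135, 10, 12, 9 and 10 did, and of the 7 of 1151 to 1157, 0, 1, 1 and 0 did. Of the 6 of 48 to 54, 1 passed in each fit, of the 4 of 1140 to 1145 0 did, and of the 5 falling loci of 1336 to 1340, 0, 3, 0 and 0 did. All loci of these runs kept their direction in each fit. This is no independent support, because they were picked by the full fit, whose other libraries these fits reuse.

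In strain 548 on porphyran, rising runs lay at 1093 to 1112 (17 called, median log2 fold change 6.06), 1121 to 1133 (13 called, 5.35), 1151 to 1157 (7 called, 6.57) and 980 to 983 (4 called, 5.77). The 4 called loci between 1326 and 1331 also rose, with a median of 3.77, from 18.2 and 27.3 RPKM to 264.8 and 305.1. The largest increases were those of 017301E_01100, from 64.6 and 61.8 RPKM to 25600 and 12500 (log2 fold change 8.35 ± 0.54, limma adjusted p = 0.00187), and 017301E_01127 (7.08 ± 0.66). The runs 1336 to 1340 and 3624 to 3627 fell here too, with medians of -4.27 and -5.83, and the named decreases were those of 017301E_03625 (-6.05 ± 0.67) and 017301E_03626 (-5.92 ± 0.59). Without galactose replicates 1 and 2 the adjusted p was 0.0607 and 0.0642 for 017301E_01127, 0.0607 and 0.0765 for 017301E_03625 and 0.0521 and 0.0637 for 017301E_03626, and without replicate 2 it was 0.0565 for 017301E_01100. The log2 fold changes in these fits were 7.18 and 6.99, -6.48 and -5.61, -6.37 and -5.44, and 8.12.

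Altogether 61 loci of strain 548 were higher and 17 lower on porphyran, and 45 of the 61 lay in 5 runs. Without galactose replicates 1 and 2 there were 11 and 0 calls (limma, with 225 and 240 loci at an unadjusted p under 0.05), and without porphyran replicates 1 and 2 there were 174 and 447. In the same order, rising runs held 4, 0, 78 and 95 loci. All 17 loci of 1093 to 1112 had an unadjusted p under 0.05 in each of these fits, though 3 and 0 of them passed the adjusted threshold without galactose replicates 1 and 2. Without galactose replicate 1, the runs 1121 to 1133 and 980 to 983 had 4 and 2 called loci. The runs 1151 to 1157, 1326 to 1331, 1336 to 1340 and 3624 to 3627 had 0 without either galactose library, with all 7, 4, 5 and 4 of their loci at an unadjusted p under 0.05. A fit on these groups alone gave 48 calls. Had no locus changed, a share of 0.05 of the 4718 tested would still have an unadjusted p under 0.05 in limma. The counts of such loci without a galactose library are about that size. Loci of the runs were picked by the full fit, so their unadjusted p without 1 library is no independent support. The porphyran libraries were the least alike of this strain, with a median absolute log2 difference of 0.962 after centring, against 0.255 on galactose and 0.455 on agarose.

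Against galactose, 51 loci of strain 548 were higher on both polysaccharides and 15 lower on both, and 0 were called in opposite directions. Independent lists would share 1.36 and 0.0649, and unchanged groups against the same galactose libraries shared 0, a value that says little, as they gave a mean of 0.19 and 0.11 calls on agarose and porphyran. Across loci the fold changes had r = 0.74 (0.50 in the simulation) and a covariance of 0.97 (0.18 in the simulation). With agarose set against galactose replicate 1 and porphyran against replicate 2, and the other way round, the covariance was 0.86 and 0.90, and 20 and 0 loci were higher on both (limma, with 0 calls and 241 loci at an unadjusted p under 0.05 on porphyran in the latter). Loci are not independent replicates, and part of the excess of shared calls may come from the shared galactose libraries. The 51 became 10 and 0 without galactose replicates 1 and 2 (limma, with 240 loci on porphyran at an unadjusted p under 0.05 in the latter), 24 and 22 without agarose replicates 1 and 2, and 134 without porphyran replicate 2.

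When agarose was compared with porphyran directly in strain 548, 1 locus was higher on agarose and 3 were lower, with 348 at an unadjusted p under 0.05. RPKM as deposited gave 1 higher and 7 lower, and quantile normalization 1 and 1. The locus 017301E_03421 was at 604 and 563 RPKM on agarose and 0.596 and 4.18 on porphyran (log2 fold change 7.74 ± 0.60, limma adjusted p = 0.0251). The loci 017301E_02839 (-6.24 ± 0.47, adjusted p = 0.0251) and 017301E_02027 (-6.70 ± 0.65, adjusted p = 0.0484) were higher on porphyran. With the replicate number as a block, all 3 named loci had an adjusted p of 0.0777 in limma. The run 1326 to 1331 had a median of -0.25 on agarose and -4.48 between the polysaccharides, where its smallest adjusted p was 0.0745. In favour of agarose, the run 48 to 54 had a median of 3.10 between them (smallest adjusted p = 0.303, 6 of 6 loci at an unadjusted p under 0.05) and the run 1121 to 1133 one of 2.39 (0.122, 9 of 13). There were 0 calls in limma with the compared groups alone (239 at an unadjusted p under 0.05), without a filter on low loci (387) and without agarose replicate 1 or 2 (328 and 146), so all 3 named calls were lost there. Their log2 fold changes without agarose replicates 1 and 2 were 7.81 and 7.73 for 017301E_03421, -6.88 and -6.53 for 017301E_02027 and -6.45 and -6.0 for 017301E_02839. In the first 2 of these fits they were the same as above by construction, since those fits use the same scaled values. Without porphyran replicates 1 and 2 there were 103 and 46 calls.

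**Figure D2:**
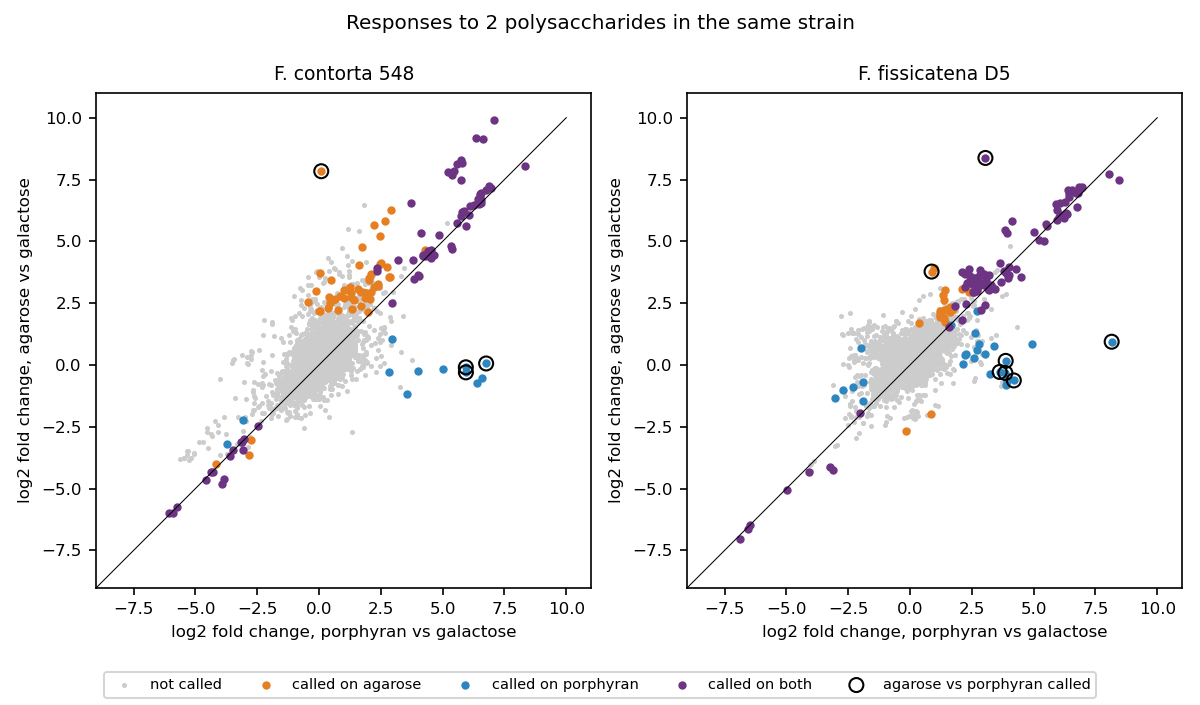
Log2 fold change on agarose (vertical axis) against that on porphyran (horizontal axis), both against the same 2 galactose libraries, for each tested locus of strains 548 and D5; the line marks equal change. Purple points, called on both polysaccharides, are 51 higher and 15 lower in strain 548 and 78 higher and 8 lower in D5, and circled points are the 4 and 7 loci called between the polysaccharides.

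On porphyran, 4 blocks of neighbouring loci within tag numbers 4400 to 4468 rose in F. contorta 588, and 1 further block at 601 to 606. The 14 called loci of 4432 to 4448 had a median log2 fold change of 6.46, with a median RPKM of 7.2 and 4.1 on galactose and 855.5 and 954.1 on porphyran. The 7 loci of 4462 to 4468 had a median of 6.50, and the 6 of 601 to 606 the steepest, 8.75. Between these blocks, the 6 loci of 4414 to 4419 fell with a median of -7.45, from 4364.8 and 1687.4 RPKM to 29.9 and 19.8.

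By locus, 017302E_unicycler_bold_00601 rose from 1.26 and 0.284 RPKM to 1090 and 5950 (log2 fold change 10.55 ± 0.89, limma adjusted p = 0.00411) and 017302E_unicycler_bold_00603 by 10.31 ± 0.73 (adjusted p = 0.00221). The decreases were led by 017302E_unicycler_bold_04415 (-8.07 ± 0.43) and 017302E_unicycler_bold_04416 (-7.58 ± 0.43), both with an adjusted p of 0.00221. There were 39 higher and 6 lower loci of 4639 tested, and 35 of the 39 lay in 5 runs. The libraries of a group differed: on galactose, the 10 loci most abundant on average in this strain held 63.3% of the summed RPKM of replicate 2 against 26.6% in replicate 1. Loci whose values equalled those of another locus in every library held 35.9% against 9.79%. Porphyran replicate 2 differed from its replicate 1 in the same way, with 41.5% against 25.3% and 18.4% against 3.91%, and after centring the median absolute log2 difference was 0.938 between the porphyran libraries and 0.355 between the galactose libraries. RPKM as deposited gave 81 higher and 9 lower. Without galactose replicate 2 there were 61 calls. Rising runs held 23 loci without porphyran replicate 1 and 23 without replicate 2, and 1 of the 4 loci of 4400 to 4403 was called in each of these fits. Simulated 5-fold changes were called in 13.4% of loci, so smaller changes were mostly not detectable in this fit. With the replicate number as a block more loci were called, as counted in the part on processing.

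In F. fissicatena D5 on agarose, 29 called loci between tag numbers 2393 and 2424 rose with a median log2 fold change of 5.99, and the 13 loci of 2439 to 2451 with a median of 6.27. The median RPKM of the first block was 5.7 and 5.5 on galactose and 557.5 and 319.5 on agarose. A weaker increase, with a median of 3.38, ran over 18 called loci of 3188 to 3210, of which 5 were called with RPKM as deposited. The 4 loci of 890 to 893 fell with a median of -6.54, from 428.3 and 453.1 RPKM to 4.1 and 2.9.

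The leading loci of strain D5 on agarose were HMPREF0240_01001, from 1.33 and 0.429 RPKM to 590 and 458 (log2 fold change 8.37 ± 0.48, limma adjusted p = 0.0034), and HMPREF0240_02406 (7.72 ± 0.39, adjusted p = 0.0034). The loci HMPREF0240_00890 (-7.02 ± 0.81, adjusted p = 0.01) and HMPREF0240_00891 (-6.61 ± 0.81, adjusted p = 0.0123) fell. Both of the former missed the threshold without galactose replicate 1 (adjusted p = 0.0576), galactose replicate 2 (0.0506) or agarose replicate 1 (0.0525), with log2 fold changes of 8.60, 8.11 and 8.42 for HMPREF0240_01001 and 7.51, 7.89 and 7.41 for HMPREF0240_02406. Without galactose replicates 1 and 2 and agarose replicates 1 and 2, in this order, the adjusted p was 0.0871, 0.0914, 0.071 and 0.0995 for HMPREF0240_00890 and 0.0963, 0.0927, 0.0857 and 0.106 for HMPREF0240_00891, with log2 fold changes of -7.31, -6.78, -7.18 and -6.87 and of -6.81, -6.45, -6.48 and -6.75.

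Of 4247 loci of strain D5 tested, 100 were higher and 10 lower on agarose, and 64 of the 85 higher at 5-fold or more lay in 4 runs, where shuffled orders gave at most 1. RPKM as deposited gave 52 and 11 calls, and a fit on these groups alone 180 and 47. Fits without 1 library reuse the other libraries, so they give no independent test of loci picked by the full fit. There were 0 calls without galactose replicate 1, galactose replicate 2 or agarose replicate 1, with 379, 349 and 326 loci at an unadjusted p under 0.05 in limma, and 4 without agarose replicate 2. Rising runs held 0 loci without any 1 of the 4 libraries, and all 29 loci of 2393 to 2424 and all 13 of 2439 to 2451 had an unadjusted p under 0.05 in these fits.

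On porphyran, strain D5 had rising runs of 31 called loci at 2390 to 2424 (median log2 fold change 6.04), 7 at 2445 to 2451 (6.37), 15 at 3188 to 3206 (2.69) and 4 at 3038 to 3042 (3.01). Of these, 30 of the 31, all 7, all 15 and all 4 were also called higher on agarose. A block at 2599 to 2605, with 5 called loci, rose with a median of 3.88. The loci HMPREF0240_02405 (8.47 ± 0.54, limma adjusted p = 0.00418) and HMPREF0240_02611 (8.16 ± 0.60, adjusted p = 0.0047) rose most among named loci. The run 890 to 893 fell with a median of -6.52, and its loci HMPREF0240_00890 and HMPREF0240_00891 had log2 fold changes of -6.87 ± 0.81 and -6.57 ± 0.81. Without galactose replicates 1 and 2 the adjusted p was 0.0529 and 0.0524 for HMPREF0240_02405, 0.0529 and 0.0526 for HMPREF0240_02611, 0.1 and 0.114 for HMPREF0240_00890 and 0.113 and 0.123 for HMPREF0240_00891. The log2 fold changes in these fits were 8.27 and 8.68, 8.02 and 8.31, -7.14 and -6.62, and -6.75 and -6.39. Without the low filter the last pair had 0.0504 and 0.0554.

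For strain D5 on porphyran 98 loci were higher and 14 lower, and 62 of the 87 higher at 5-fold or more lay in 5 runs. RPKM as deposited gave 65 and 8, with 0 of the 15 loci of 3188 to 3206 called in limma and 15 at an unadjusted p under 0.05. There were 41 calls without the low filter and 49 with these groups alone. As on agarose, fits without 1 library give no independent test of loci picked by the full fit. Porphyran replicate 1 stood apart, with a summed RPKM of 1031025 against 623814 to 709035 in the other libraries and 8.11% of it in the highest locus, against 24.1% to 32.3% in the others. Without it 190 loci were called, without porphyran replicate 2 there were 624, and without galactose replicates 1 and 2 there were 0 and 7 in limma (388 and 352 at an unadjusted p under 0.05). Rising runs held 0 and 5 loci without galactose replicates 1 and 2, and in both fits all 31 loci of 2390 to 2424 had an unadjusted p under 0.05. Of the 15 loci of 3188 to 3206, 6 were called without porphyran replicate 1.

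On both polysaccharides, 78 loci of strain D5 were higher and 8 lower, with 0 in opposite directions; independent lists would share 2.31 and 0.033, and the simulated unchanged groups shared 0, with a mean of only 0.18 and 0.12 calls to share. The covariance of the fold changes across loci was 0.74, against 0.15 in the simulation, and r was 0.71 against 0.50. With a separate galactose library for each polysaccharide (replicate 1 for agarose, then replicate 2), the covariance was 0.57 and 0.61, and 8 and 0 loci were higher on both (limma, with 0 calls and 381 loci at an unadjusted p under 0.05 on agarose in the latter). Part of the excess of shared calls may come from the shared galactose libraries. The 78 became 0 without galactose replicate 1, galactose replicate 2 or agarose replicate 1, where 0 loci were called on agarose in limma with 379, 349 and 326 at an unadjusted p under 0.05. They became 3 without agarose replicate 2 and 137 without porphyran replicate 2.

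Directly compared in strain D5, 2 loci were higher on agarose than on porphyran and 5 were lower, with 383 at an unadjusted p under 0.05. RPKM as deposited gave 1 and 9, and quantile normalization 1 and 5. HMPREF0240_01001 was higher on agarose (5.32 ± 0.48, limma adjusted p = 0.0388), as was HMPREF0240_02250 (2.91 ± 0.31, adjusted p = 0.0466), while HMPREF0240_02611 (-7.21 ± 0.60, adjusted p = 0.0386) and HMPREF0240_02605 (-4.82 ± 0.47, adjusted p = 0.0397) were higher on porphyran. With the replicate number as a block, the 4 named loci had an adjusted p from 0.094 to 0.13 in limma. The run 2599 to 2605 had a median of -0.62 on agarose and of -4.59 between the polysaccharides, where 2 of its 5 called loci passed the test. With the compared groups alone (317 at an unadjusted p under 0.05 in limma), without a filter on low loci (434) and without agarose replicate 1 or 2 (206 and 163) there were 0 calls, so the 4 named calls were lost. Their log2 fold changes without agarose replicates 1 and 2 were 5.36 and 5.28 for HMPREF0240_01001, 2.87 and 2.94 for HMPREF0240_02250, -7.46 and -7.00 for HMPREF0240_02611 and -4.78 and -4.88 for HMPREF0240_02605. In the first 2 of these fits they were as given above by construction, since those fits use the same scaled values. Without porphyran replicates 1 and 2 there were 117 and 26 calls.

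**Figure D3:**
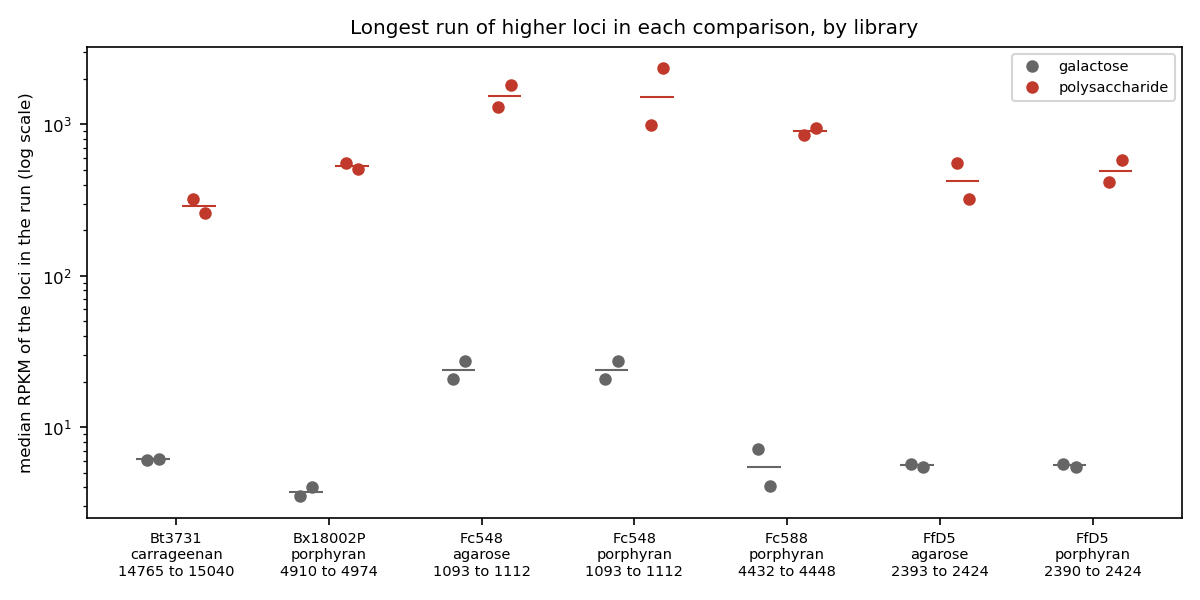
Median RPKM (vertical axis, log scale) over the called loci of the longest rising run in each comparison (horizontal axis), as 1 point per library; the bars are geometric means of the 2 libraries, and the tables of the strains were processed separately. The galactose points lie between 3.5 and 27.4 RPKM and the polysaccharide points between 261.1 and 2345.4.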

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

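The comparison of agarose with porphyran was fixed before the data were examined and the bound on the spread of low loci before its value was seen; the other tests in this part were chosen after the results were seen.

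Some loci responded differently to agarose and porphyran in the same strain by the direct comparison of the polysaccharides: 4 in strain 548 and 7 in strain D5. In strain 548 these included 017301E_03421, with a log2 difference of 7.74 in favour of agarose, and 017301E_02027 and 017301E_02839, with -6.70 and -6.24. In strain D5, HMPREF0240_01001 (5.32) and HMPREF0240_02250 (2.91) were higher on agarose, and HMPREF0240_02611 (-7.21) and HMPREF0240_02605 (-4.82) higher on porphyran. With the replicate number as a block, all 7 named loci missed the threshold in limma, with an adjusted p from 0.0777 to 0.13. None of these 7 named loci passed the threshold in limma with the compared groups alone (239 loci of strain 548 and 317 of D5 at an unadjusted p under 0.05), without the filter on low loci (387 and 434), without agarose replicate 1 (328 and 206) or without agarose replicate 2 (146 and 163). By construction, their log2 differences were the same with the compared groups alone and without the filter, as these fits share the scaled values. This sameness is therefore no support. Without agarose replicates 1 and 2 the differences were 7.81 and 7.73 for 017301E_03421 and -7.46 and -7.00 for HMPREF0240_02611, for example, so the calls ended by the adjusted p. Had no locus changed, a share of 0.05 of the tested loci would still have an unadjusted p under 0.05 in limma. The counts without agarose replicate 2 were no larger than that share.

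In strain 3731, loci of low abundance stood higher in carrageenan replicate 1 than in replicate 2, by a median log2 ratio of 1.20 among the lowest of 3 equal parts of the loci by mean level. A single scaling factor is argued against by the gap of 1.14 between the lowest and the highest of these parts. Shallow counting as the only source is argued against by the loci at the floor. Replicate 1 had a relative depth of 0.68 to replicate 2, and galactose replicate 1 one of 0.62 to its replicate 2. Fewer reads alone would leave more loci at the floor, but these shallower libraries had 91 against 150 and 55 against 259. The levels of the galactose pair cannot tell: its replicate 1 stood higher in the lowest part too, by 0.43, so a smaller share of shallow counting is not excluded. Reads spread evenly over the genome would put loci that are silent on galactose near 1 common level; among 621 loci under 2 RPKM in both galactose libraries the interquartile range was 1.20 times the median of 11.02 RPKM (1.03 to 1.36 over 95% of 1000 resamples of loci), past the bound of 1 set for it. An uneven background stays open, and no biological explanation was tested, since both libraries came from the same carbon source.

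In strain 588, most loci of galactose replicate 2 stood at a median log2 ratio of -0.98 to replicate 1. The relative depth of replicate 2 was 1.27, so it was not the shallower library. RPKM is divided by the library total, so depth by itself would not move the levels and this value cannot decide. A few loci taking most of the reads may account for it: the 10 loci most abundant in the other 3 libraries held 63.3% of summed RPKM in replicate 2 and 26.6% in replicate 1, and outside them the log2 ratio of the sums was -0.82, within 0.17 of the shift, while over all loci it was 0.18. No biological explanation was tested, since both libraries came from the same carbon source.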

How the results depend on the processing

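Chosen before the data were examined were the thresholds on adjusted p and fold, the fit without a filter on low loci, the compared groups alone, the replicate block and leaving out libraries for the comparisons, the fold for the overlaps, and the fold, gap and length for the runs; all others, and these other settings for overlaps and runs, were added after the data were seen. Not run were the count models with their size factors, library sizes without ribosomal and transfer RNA, the gene lists, and the adjustment or centring of an authors' comparison table, because the unit was RPKM and the tables give no product names. Counts are of called loci in limma unless runs are named; the cause of a change was not tested, except that stricter thresholds and fewer loci or libraries act by construction. Absolute depth is unknown, which limits low loci.

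An adjusted p under 0.01 gave 468 calls in strain 3731, 1164 in 18002P, 51 and 44 in 548 on agarose and porphyran, 44 and 28 in D5, and 0 in both comparisons of agarose with porphyran, where 348 and 383 had an unadjusted p under 0.05. A fold of at least 2 left 625 in 18002P, and one of at least 5 left 404 in 3731 and 267 in 18002P. Without the variance trend 3731 had 665. The authors' deposited p-values under 0.05 numbered 7 in 3731 and 643 in 18002P, of which 5 and 575 were called here.

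Replicate numbers were not treated as pairs: the difference between libraries 1 and 2 of a group correlated across loci with that of another group by 0.13 in 3731, -0.32 in 18002P, 0.07 to 0.16 in 548, 0.21 in 588 and 0.01 to 0.43 in D5. With the replicate number as a block there were 2357 calls in 3731, 176 in 588 (84 loci in rising runs) and 0 between agarose and porphyran in 548 and D5 (442 and 385 at an unadjusted p under 0.05); the other counts stayed within 1.5 times, 1746 in 18002P among them. Of the 15 loci of 3188 to 3206 in D5 on porphyran, 0 were then called in limma, with 15 at an unadjusted p under 0.05. With the numbers of 1 group crossed, chosen after that negative correlation was seen, 18002P had 2135.

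With the 2 compared groups alone, 548 had 333 on agarose, 48 on porphyran and 0 between them (239 unadjusted), D5 had 227, 49 and 0 (317 unadjusted), and the overlap of D5 was 38. RPKM as deposited gave 8 between agarose and porphyran in 548, 90 in 588, 63 and 73 in D5 on agarose and porphyran, an overlap of 43 and 36 loci in rising runs of D5 on agarose. Quantile normalization gave 2 between agarose and porphyran in 548. A pseudocount of 0.1 gave 2 in that comparison in both strains, and one of 5 an overlap of 45 and 33 loci in rising runs on porphyran in D5. Without the filter on low loci, D5 had 41 on porphyran and an overlap of 29, and both comparisons of agarose with porphyran had 0 (387 and 434 unadjusted). At a mean of at least 50 RPKM, 548 had 78 on agarose and 2 between agarose and porphyran, and D5 had 50, 53 and 1, with an overlap of 39.

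For runs, a fold of at least 2 put 359 loci in rising runs of 3731, and one of at least 10 put 89 there, 41 in D5 on agarose and 38 on porphyran. Allowing no other loci between neighbours left 44 in 548 on agarose.

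Leaving out 1 library, with the lone library assumed to vary like the other groups, gave 705 to 3325 calls in 3731, 1393 to 1946 in 18002P, 25 to 33 in 548 on agarose, 0 to 447 on porphyran and 0 to 103 between them, 36 to 66 in 588, and 0 to 4, 0 to 624 and 0 to 117 in D5 in the same order. Where such a count was 0, between 146 and 388 loci had an unadjusted p under 0.05. The overlap ran from 0 to 134 in 548 and from 0 to 137 in D5, and with a separate galactose library for each polysaccharide it was 20 and 0 in 548 (241 unadjusted on porphyran where it was 0) and 8 and 0 in D5 (381 on agarose). Loci in rising runs ranged from 108 to 440 in 3731, 175 to 182 in 18002P, 17 to 24 and 0 to 95 in 548, 23 to 42 in 588, 0 in D5 on agarose and 0 to 93 on porphyran; between agarose and porphyran they ranged from 0 to 20 in 548 and 0 to 10 in D5. Among the symbols, araD ranged from -1.04 without carrageenan replicate 1 to 0.62 without replicate 2, and ssrA from -0.43 to 0.49, with -0.09 without galactose replicate 2. Named loci with tags kept their direction in every alternative; leaving out libraries aside, 331 of their values kept the threshold and 45 lost it, and leaving out a library 90 kept it and 50 lost it.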

Other observations

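The tests in this part were chosen after the results were seen.

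The falling runs called in the Faecalicatena strains were short but steep. Simulated 5-fold changes were called in 56.7% of loci in 548 and 71.6% in D5 on agarose, and in 13.4% in 588. Shallower falling runs could therefore be missed. In both strains grown on 2 polysaccharides, a run of 4 loci fell by more than 5 log2 units at its median on each of them: 3624 to 3627 in strain 548 (-5.88 on agarose and -5.83 on porphyran) and 890 to 893 in strain D5 (-6.54 and -6.52). The galactose libraries held these loci at medians of 146.9 and 356.2 RPKM in strain 548 and 428.3 and 453.1 in D5. Within a strain, both polysaccharides were compared with these same galactose libraries. The near-equal medians on agarose and porphyran are therefore not independent of each other. In limma 0 of the 4 loci passed the adjusted threshold without either galactose library in D5 and in strain 548 on porphyran, nor without either agarose library in both strains; in strain 548 on agarose 2 passed without galactose replicate 1 and 0 without replicate 2. All 4 kept their direction in each of these fits, but they were picked by the full fit, so this is no independent support. Whether the runs hold related genes was not tested, because the tags of different strains are not matched here.

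Rising runs took shares of summed RPKM in the Faecalicatena strains that overlapped those in the Bacteroides strains, with each table processed separately. In strain 3731 the shares were 4.01% and 4.51% on carrageenan, and in 18002P 8.08% and 6.88% on porphyran. In strain 588 they were 3.52% and 4.59% on porphyran, in D5 4.73% and 3.37% on agarose and 4.42% and 6.75% on porphyran, and in strain 548 8.06% and 7.35% on agarose and 4.71% and 7.75% on porphyran. On galactose the same loci took between 0.03% and 0.14% in the Faecalicatena strains.

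Some falling runs lay close to rising runs: 1336 to 1340 in strain 548 was 5 positions from 1331, 4414 to 4419 in strain 588 was 11 positions from 4403, and 1007 to 1016 in strain 18002P was 16 positions from 991. The hypothesis was that falling runs may sit beside rising ones more often than random placement gives. Of 9 falling runs, 3 were within 20 loci of a rising run, a distance picked after the positions were seen, against a mean of 1.08 over 10000 random placements. Placements with as many made up 0.08 of the draws, so chance placement is not excluded.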
